A study of Homo sapiens with 8 samples.

How the data were processed

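The measurements are counts of library elements in 8 sequenced libraries of PCR amplicons from genomic DNA of K562 cells. Per the labels, cells were recruited with doxycycline for 2 or 5 days, and each library is the Bound or the Unbound fraction of replicate 1 or 2 of one screen. Replicates are numbered in the labels, which do not say whether they are separate infections or cultures, so p-values measure the spread between these libraries, which may be technical. Groups were taken from the sample titles. The deposited tables name the day 2 screen for activation and the day 5 screen for repression, and the minimal promoter was ascribed to DY032 and the constitutive promoter to JT039 on that ground, since no label states it. The deposited tables name their columns ON and OFF. ON was read as Bound and OFF as Unbound, because Bound cells are those with the reporter's surface marker in this method. The labels do not state this pairing outright, and a reversed pairing would turn the sign of every score.

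The authors deposited raw counts per element, made with Bowtie2 per the submitters' processing notes, with the version, library reference and trimming not given in the sources used here. The smallest deposited count is 5, so the authors applied a minimum of 5 before deposit, as a filter or as a floor. In the tested elements, 3 in the activation screen and 2 in the repression screen hold such a count in a library. The authors also deposited log2 scores, which equal log2 of OFF over ON after division by the column totals to within 1e-06 in every element with a score, and a standard error, which equals the absolute difference of the replicate scores divided by 2. The deposited scores were used only as an alternative. They run from high in the OFF fraction, so their sign was turned for activation.

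Element labels give a protein identifier, a tile number, the residues mutated and the substitution. The 76 protein identifiers were set against the symbols, synonyms, RefSeq proteins and gene numbers of the human gene table given here, and 0 matched. The identifiers have the form used by UniProt, which none of those entries has. The lack of matches therefore does not say which organism the proteins come from. No element carries a gene name. The gene lists fixed in advance (nuclear receptors, coactivators, corepressors and transcription factor families) could thus not be applied. Proteins are named by identifier, with at most 2 tiles or mutants at each end of a comparison. The labels place mutations in 85 tiles, of which 24 only receive motifs, and name 102 motif sites. Labels that join a tile to another tile's motif were read as that motif placed into the tile.

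Elements with at least 20 counts over both fractions in each replicate were kept, which removed 5 elements in the activation screen and 6 in the repression screen. Median counts per element ranged from 374.5 to 902 over the libraries. Scores used a pseudocount of 1 and were centred per replicate on the median of the 40 random controls. Score tests used edgeR 4.0.16 (quasi-likelihood, R 4.3.3) on Bound against Unbound with the replicate number as a block and offsets that centre the controls. The block is in the design because the study's score is a ratio within a separation. Replicate libraries differed beyond sampling noise, with a chi-square per degree of freedom of 4.77, 3.27, 3.57 and 21.9 over the activation Bound, activation Unbound, repression Bound and repression Unbound libraries. None were counted as duplicates. An element was called at a Benjamini-Hochberg adjusted p under 0.05 with the same direction in both replicates.

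Mutant minus unmutated differences were taken within each replicate and tested with limma 3.58.1. Class effects are medians over tiles, after averaging the motif sites of a tile. They were tested by a two-sided sign-flip test of the median, exact under 10 tiles and otherwise with 100000 resamples, and adjusted over the 25 classes. Flipping values below the median leaves the median unchanged, so the smallest p of this test is 0.062 with 8 tiles and 0.002 with 19. Where groups of tiles were compared, tile labels were permuted, exactly where a group had under 10 tiles. The test summed over classes used random permutations instead. The contrasts between residues within a motif and the comparison of tile groups were chosen after the data were examined, as were 3 added alternatives: leaving out elements at a count of 5, taking the protein as the unit, and choosing tiles on replicate 1 while measuring on replicate 2. The residue contrasts were adjusted over 32 tests. The other alternatives were fixed before the data were examined: TMM, DESeq2 1.42.0 size factors and Wald test, no replicate block, other count minimums (1 and 100), a pseudocount of 5, tiles past the score threshold alone, the deposited scores, the control range, an edgeR interaction fit, and each replicate left out. Named elements follow a rule fixed in advance: the largest scores, falls and rises past the threshold, the highest unmutated tiles, and those past the threshold in both screens. The lowest unmutated tiles, and the elements named in the closing section, were chosen after their values were seen.

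The steps were tested on simulated counts, of which 200 elements were changed by a known amount. Each element had its mean count over all libraries in both fractions, and the spread typical of that count level. Simulated tiles thus began balanced between the fractions, unlike real tiles with strong scores. The rates that follow need not hold for mutants of such tiles. For a change of 1 (log2) the score test recovered 100% in the activation screen (1829 elements) and 95.1% in the repression screen (1827 elements). For a change of 0.5 it recovered 84.3% and 34.3%. For differences of 1 between mutant and tile, limma recovered 100% of those among 1684 activation pairs and 55.7% of those among 1683 repression pairs. Of all calls made on the simulated counts, 3.6% and 7.9% fell on unchanged elements in the score test, and 10.9% and 4.6% in the difference test, where mutants share their tile's error. The repression screen is therefore the less precise. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 made the remaining calculations and plots. PCR counts are without molecular identifiers here, so counts are not independent molecules.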

Results

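K562 cells, an established human line from a chronic myelogenous leukaemia, carried a pooled library of short protein tiles fused to rTetR, a DNA-binding domain that doxycycline brings to a reporter gene. The library changed short motif sites residue by residue, with positions numbered as in the LxxLL motif. LxxLL is the leucine-rich box through which many coregulators contact nuclear receptors. Many of the sites differ from LxxLL, as mutants that make all its leucine positions leucine were measured in 55 tiles. Cells were parted on magnetic beads into a Bound and an Unbound fraction, and the library elements in each fraction were counted. On day 2 the reporter DY032 was read for activation, and on day 5 the reporter JT039 was read for repression. The study used a minimal and a constitutively active promoter, taken here as those of the activation and the repression reporter. Each screen had 2 replicates of each fraction, which makes 4 libraries per screen and 8 in all. Total counts in the activation screen were 1617660 and 1224731 in the Bound libraries and 1297842 and 1853448 in the Unbound libraries. In the repression screen they were 926006 and 799802 in the Bound libraries and 1919493 and 2308714 in the Unbound libraries.

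After the count minimum, 1829 elements were tested in the activation screen and 1827 in the repression screen. They held 59 unmutated tiles that had mutants, 24 further unmutated tiles that received motifs from other tiles, and 190 of those recipient tiles carrying a foreign motif. They also held 77 artificial constructs and 40 random control sequences. The mutants numbered 1439 in the activation screen and 1437 in the repression screen. Of these, 1418 and 1417 had a measured unmutated tile. The score is log2 Bound over Unbound for activation and log2 Unbound over Bound for repression, with the median random control of each replicate set to 0. The replicate scores correlated across elements with Pearson's r = 0.981 and Spearman's rho = 0.973 in the activation screen, and with r = 0.944 and rho = 0.905 in the repression screen. Elements are not independent replicates, so these coefficients describe precision only. The median SD between the replicate scores of an element was 0.115 in the activation screen and 0.183 in the repression screen.

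The first comparison asked which tiles turned the silent reporter on. Of the 59 unmutated tiles, 34 scored higher than the random controls and 21 scored lower, at an adjusted p under 0.05 from edgeR's quasi-likelihood test with the same direction in both replicates. The highest-scoring tile was F5HCV3_058, at 4.94 ± 0.23 (SD, n = 2; adjusted p = 9e-321). It was followed by Q2HR71_028, at 4.63 ± 0.10 (SD, n = 2; adjusted p = 6.4e-260). At the other end, C0H677_035 scored -2.91 ± 0.49 (SD, n = 2; adjusted p = 2.6e-74) and P52534_006 scored -2.64 ± 0.03 (SD, n = 2; adjusted p = 6.3e-53). Among mutants, 742 scored higher and 439 lower by the test, and 572 lay above and 229 below the range of the controls given below. Of the 24 tiles chosen to receive motifs, 17 were called higher and 1 lower, with a median score of 0.34 and a highest score of 0.71, inside the range of the controls.

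The random controls spread more widely than their replicates did. Their SD was 0.43 in the activation screen, against a median replicate SD of 0.11, and 22 of the 40 controls themselves passed the test against their own median. The control range, taken as 2 control SDs on each side of the control mean, ran from -0.91 to 0.81. The highest control, random-06, scored 0.67 ± 0.17 (SD, n = 2) and the lowest, random-11, scored -1.18 ± 0.33 (SD, n = 2). By this range 33 unmutated tiles lay above the controls and 10 below. Over all elements, 938 were called higher and 494 lower by the test, and 607 and 241 lay outside the control range. TMM scaling moved the median score by -0.33 and the split to 710 higher and 739 lower. DESeq2's size factors moved it by -0.30 and the split to 736 and 720. The counts under both scalings used the adjusted p alone, without the rule on direction in both replicates. Both scalings left 34 unmutated tiles higher.

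The second comparison asked which tiles silenced the active reporter. Of the 59 unmutated tiles, 43 scored higher for repression and 9 scored lower (edgeR's quasi-likelihood test, adjusted p under 0.05). The strongest was Q69138_004, at 4.19 ± 0.13 (SD, n = 2; adjusted p = 1.4e-106), then P28277_014, at 4.11 ± 0.34 (SD, n = 2; adjusted p = 1.9e-132). The lowest were P03169_002, at -2.46 ± 0.15 (SD, n = 2; adjusted p = 2.4e-15), and P09310_002, at -2.11 ± 0.22 (SD, n = 2; adjusted p = 8.4e-10). Among mutants, 619 scored higher and 347 lower by the test, and 517 lay above and 164 below the control range. Of the 24 recipient tiles, 1 passed. The control SD was 0.41, the control range ran from -0.88 to 0.77, and 7 of the 40 controls were called. The highest control, random-40, scored 1.32 ± 0.36 (SD, n = 2) and the lowest, random-35, scored -1.03 ± 0.27 (SD, n = 2). By the control range 43 unmutated tiles lay above and 4 below. Over all elements, 707 were called higher and 367 lower, and 569 and 172 lay outside the control range. TMM scaling moved the median score by -0.21 and gave 622 higher and 548 lower. DESeq2's size factors moved it by -0.19 and gave 624 and 533. Here too the counts under both scalings used the adjusted p alone.

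Set against each other, the screens sorted the 59 unmutated tiles into 16 higher in activation only, 25 higher in repression only and 18 higher in both. No tile was higher in neither screen. It follows that the 21 tiles below the controls in the activation screen were all higher in the repression screen, and the 9 below in the repression screen all higher in the activation screen. Under independence 24.78 tiles would be higher in both, and Fisher's exact test, two-sided, gave p = 2.1e-05 for the 18 seen. Tiles higher in neither screen are lacking from this set, so the test describes the set and not proteins at large. With 34 and 43 of 59 tiles higher and none in neither, the overlap can only be 18. The p thus reflects the lack of such tiles and is no separate evidence that the activities exclude each other. Some tiles come from one protein and share a motif site, such as Q2HR71_028 and Q2HR71_031, so tiles are not all independent. The test was not repeated with the protein as the unit. Across the 59 tiles the activation and repression scores had Pearson's r = -0.49 and Spearman's rho = -0.50. The lack of tiles higher in neither screen favours negative values here too. Across all 1827 elements r was -0.09 and rho -0.05. Q2HR71_028 was among the elements high in both, with a repression score of 2.96 ± 0.08 (SD, n = 2; adjusted p = 8e-51 by edgeR).

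**Figure D1:**
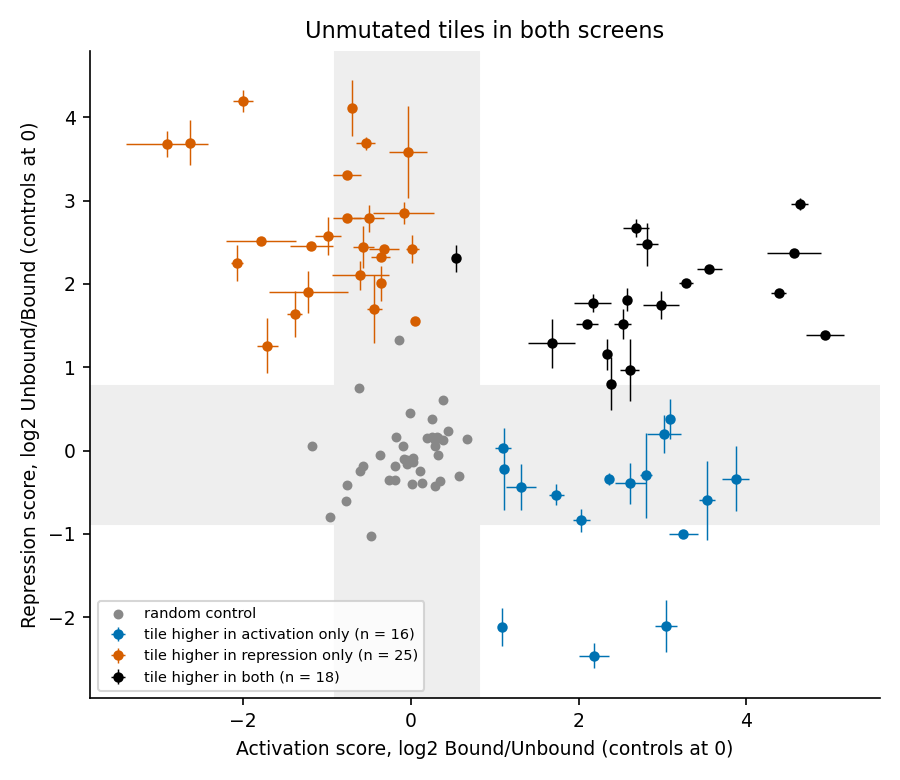
Each point is an unmutated tile or a random control, with its activation score on the x axis and its repression score on the y axis (both log2, mean of 2 replicates, random controls centred at 0). Bars are the SD of the replicates, and grey bands mark the control range of each screen. Of the 59 tiles, 25 were called higher in repression only, 16 in activation only and 18 in both.

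The mutants show what these activities needed. Motif positions 1, 4 and 5, where LxxLL has its leucines, were replaced by alanine together (labelled 1A-4A-5A). This lowered activation in 33 of the 34 tiles that scored higher for activation. The median difference from the unmutated tile was -2.24 (SD over tiles 1.13; adjusted p = 0.00025, two-sided sign-flip permutation test). It lowered repression in 41 of the 43 repressing tiles, with a median of -2.11 (SD over tiles 1.25; adjusted p = 0.00025). The largest fall in activation was in F5HCV3_060, where a 1A-4A-5A mutant brought the score from 4.39 to -0.24 ± 0.21 (SD, n = 2; adjusted p of the difference 1.6e-126 by limma). The named site of this mutant overlaps another in the tile, so the mutant also changes that other site. The tile with the next largest fall was Q2HR73_062, which went from 3.53 to -0.81 ± 0.36 with 1A-4A-5A (SD, n = 2; adjusted p of the difference 1.3e-113 by limma). In repression, Q69138_004 fell when uncharged residues in the stretch holding its motif became aspartate. Its score went from 4.19 to -0.96 ± 0.15 (SD, n = 2, adjusted p of the difference 7.3e-06 by limma). P52534_006 went from 3.69 to -0.99 ± 0.12 with 1A-4A-5A (SD, n = 2; adjusted p of the difference 7.3e-06 by limma).

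Counted one by one with limma on the differences within each replicate, 573 of 1418 mutants scored lower than their unmutated tile for activation and 267 scored higher. For repression 565 of 1417 scored lower and 94 higher. These tests measure the spread between replicates and not the wider spread between control elements. Of 76 artificial constructs, 7 were called lower and 14 higher in activation than their form without a motif. All 76 lay in the control range. By size, 318 mutants fell by over 1 in activation and 468 in repression. In tiles that had scored higher in the screen, 525 of 849 mutants fell in activation and 78 rose, and 527 of 919 fell in repression and 28 rose. Most rises in the activation screen came from the other tiles, where 189 of 569 mutants rose. The largest were in tiles far below the controls. C0H677_035 went from -2.91 to 0.03 ± 0.21 with 1L-4L-5L (SD, n = 2; adjusted p of the difference 5e-57 by limma). P52534_006 rose when charged residues in the stretch holding its motif became alanine. Its score went from -2.64 to -0.16 ± 0.12 (SD, n = 2, adjusted p of the difference 9.3e-42 by limma). In repression the largest rise was a tryptophan at position 4 of P03186_304, which took the score from -0.44 to 4.17 ± 0.14 (SD, n = 2; adjusted p of the difference 7.3e-06 by limma). The second, arginine at position 2 of Q9QJ12_059, took it from 2.57 to 4.65 ± 0.07 (SD, n = 2; adjusted p of the difference 0.00015 by limma). Mutants of one tile share the error of that tile's score.

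The third comparison asked which position and which kind of residue mattered. Positions are numbered as in LxxLL, where 1, 4 and 5 are the leucines. Positions 2 and 3 lie between them, and -1, 0 and 6 flank them. The labels do not give the unmutated residues. A 1L-4L-5L mutant differs from its tile only where some of these positions are not leucine, and 88 such mutants were measured in 55 tiles. Many sites thus do not hold LxxLL, and a class can replace residues other than leucine. Over all tiles, 12 of the 25 mutation classes lowered activation and 14 lowered repression. No class raised either, and none with a median above 0 had an unadjusted p under 0.05 (sign-flip permutation test over tiles). The values that follow are medians over the tiles that scored higher in the screen. There 17 classes lowered activation and all 25 lowered repression. These tiles were chosen on the same unmutated score that is then subtracted, so the choice by itself favours lower differences. With tiles chosen on replicate 1 and differences from replicate 2, 16 classes were lower in activation and 25 in repression. That split does not remove a deviation of the unmutated tile that both replicates share.

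Alanine lowered both activities at each of positions 1, 4 and 5. In activation the median difference was -2.01 at position 1 (SD over tiles 0.93), -1.39 at position 4 (SD 0.66) and -1.56 at position 5 (SD 0.65). All 19 tiles were lower at each of the positions, and the adjusted p was 0.0037 for each by sign-flip permutation. With 19 tiles the smallest unadjusted p this test can give is 0.002. In repression the medians were -2.07 at position 1 (SD 1.24), -1.83 at position 4 (SD 1.23) and -1.64 at position 5 (SD 1.16). There 23, 22 and 23 of 24 tiles were lower, with an adjusted p of 0.0011 for each by permutation. Valine at position 1, 4 and 5 gave -1.65, -0.91 and -1.03 in activation and -1.84, -0.81 and -1.21 in repression. Compared within the same motif, valine left more activation than alanine at all 3 positions, by a median of 0.46, 0.28 and 0.31 (adjusted p = 0.01 each, sign-flip permutation test).

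Aromatic residues at positions 1, 4 and 5 left more of both activities than alanine did. In activation, phenylalanine or tryptophan gave a median of -0.26 at position 1 (adjusted p = 0.054), -0.04 at position 4 (adjusted p = 1) and -0.18 at position 5 (adjusted p = 0.21). None of the 3 passed the permutation test. In repression the medians were -0.58, -0.41 and -0.52, and all 3 passed (adjusted p = 0.0043, 0.0029 and 0.0011 by permutation). Within the same motif, phenylalanine kept more activation than alanine by a median of 1.5 at position 1, 1.21 at position 4 and 1.24 at position 5 (adjusted p = 0.012, 0.01 and 0.012 by permutation). The same contrast in repression was 0.78, 1.22 and 0.70 (adjusted p = 0.01, 0.012 and 0.031 by permutation). Tryptophan and phenylalanine were not told apart at any of these positions in either screen. The lowest adjusted p of those 6 contrasts was 0.12.

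At positions 2, 3 and 6, basic residues lowered activation more than acidic ones. Basic residues lowered it at position 2 (median -0.87), position 3 (-0.71) and position 6 (-1.03), each with an adjusted p of 0.0037 by permutation. Acidic residues at the same positions gave -0.26, -0.01 and -0.05, and none of these passed (adjusted p = 0.081, 0.85 and 0.75 by permutation). At position -1, where no basic residue was tried, acidic residues lowered activation by a median of -0.31 in 15 tiles, of which 12 were lower (adjusted p = 0.012 by permutation). With tiles chosen on replicate 1 and differences taken from replicate 2 the median for acidic residues at position -1 was -0.12 and the class no longer passed. Within the same motif, aspartate left more activation than lysine by a median of 0.87 at position 2, 0.69 at position 3 and 0.69 at position 6 (adjusted p = 0.02, 0.02 and 0.012 by permutation). The corresponding contrasts in repression were -0.45, -0.29 and -0.03, and none passed (adjusted p = 0.19, 0.68 and 0.75 by permutation). Acidic residues at position 2 had a median of -2.05 in repression (SD over tiles 1.43), with 18 of 22 tiles lower (adjusted p = 0.0011 by permutation). Proline at position 3, which breaks a helix, lowered activation by a median of -1.20 (SD over tiles 0.69) in all 19 tiles and repression by a median of -2.29 (SD over tiles 1.39) in 23 of 24 tiles (adjusted p = 0.0037 and 0.0011 by permutation). Over all tiles the proline class had a median of -0.28 in activation (adjusted p = 0.046 by permutation). With the protein as the unit the median was -0.43 and the class no longer passed.

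Substitutions at several positions also lowered both activities. Making all 3 motif positions leucine (1L-4L-5L) gave a median of -0.47 in activation and -0.61 in repression. Methionine, leucine and methionine (1M-4L-5M) gave -1.53 and -1.83. Labels give only a stretch holding the motif for the next changes, and do not say whether positions 1, 4 and 5 were spared. Turning charged residues of that stretch to alanine gave -1.09 in activation and -1.01 in repression. Turning its uncharged residues to aspartate gave -1.39 and -2.16. All of these passed the permutation test, with an adjusted p of 0.0032, 0.0037, 0.0037 and 0.0037 in activation and 0.00025, 0.0011, 0.0043 and 0.002 in repression. Over all tiles, charged residues to alanine passed in neither screen (-0.09 and -0.23, adjusted p = 0.76 and 0.25 by permutation). In activation 1L-4L-5L (-0.11) and 1M-4L-5M (-0.21) did not pass there either (adjusted p = 0.46 and 0.13 by permutation). The rest of these passed over all tiles.

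**Figure D2:**
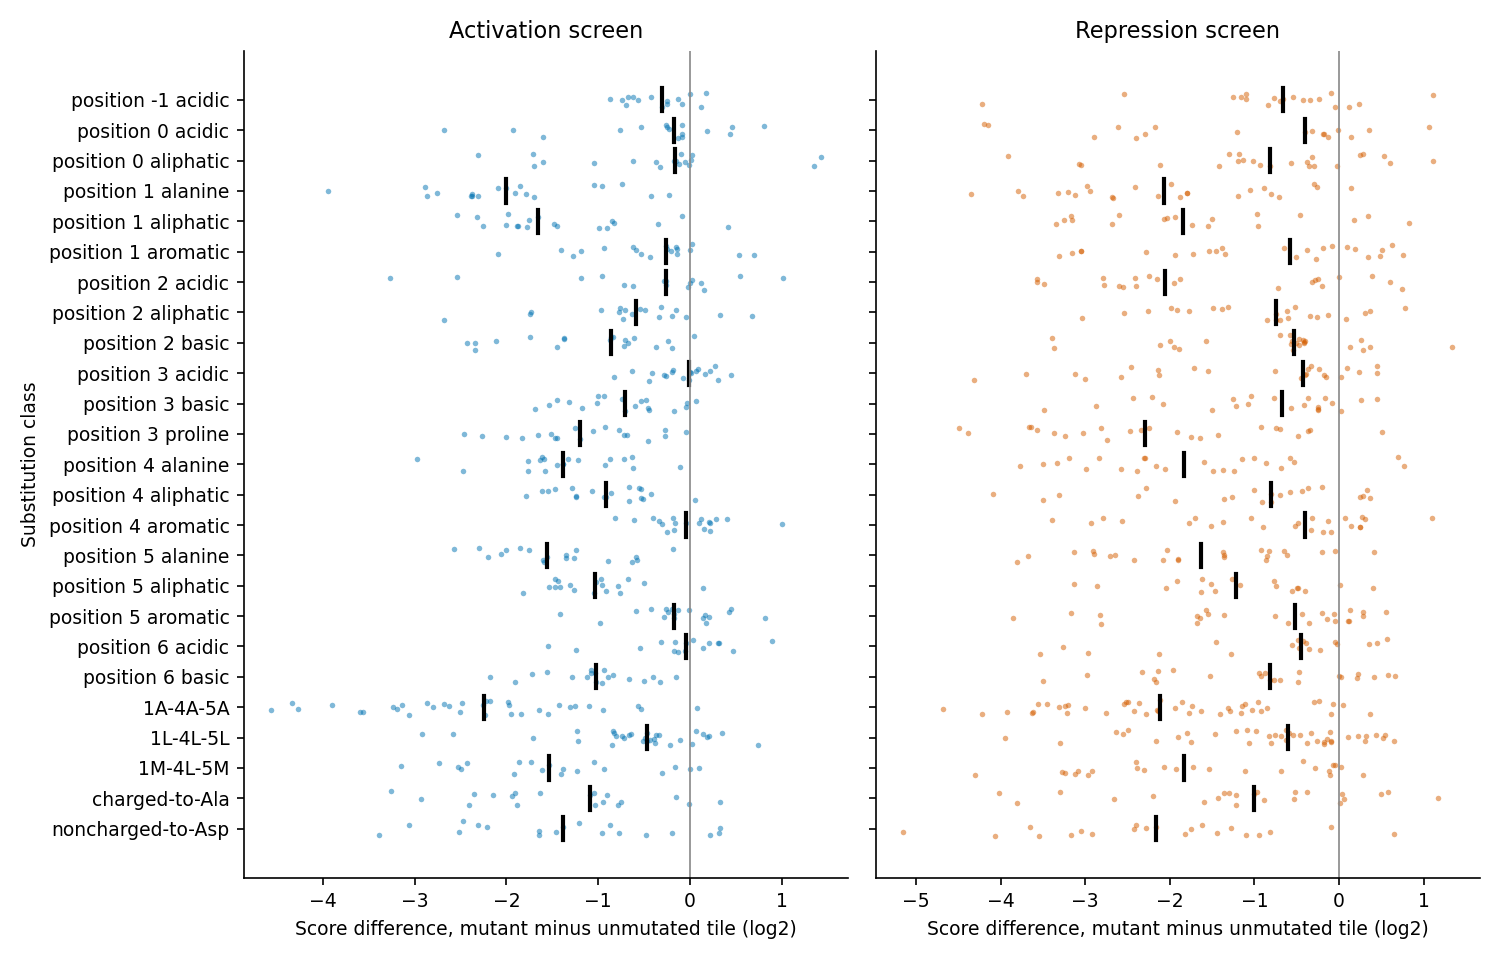
Each point is a tile that scored higher in the screen, placed by its mutant minus unmutated score difference (x axis, log2) for the substitution class named on the y axis. Black bars are medians over tiles, the left panel is the activation screen and the right panel the repression screen. The 1A-4A-5A class has medians of -2.24 and -2.11, while aromatic residues at position 4 have medians of -0.04 and -0.41.

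The class medians of the screens come from different tiles. Among the 18 tiles higher in both, 1A-4A-5A was measured in 18, 1L-4L-5L in 16 and each other class in 6 to 8. A sign-flip test of the median over 6 to 8 tiles cannot give a p under 0.062, so for those classes a difference between the screens is left open. Charged residues to alanine reached that smallest value, with a median activation minus repression difference of -0.87 (SD over tiles 0.79; 8 tiles, exact p = 0.062). Of the classes with more tiles, 1A-4A-5A had a median activation minus repression difference of -0.31 (SD over tiles 0.63; permutation p = 0.18) and 1L-4L-5L of -0.19 (SD over tiles 0.66; permutation p = 0.45). In the repression screen, acidic residues at position 2 had a median of -0.30 in 6 tiles called higher in both screens and -2.41 in 16 tiles called in repression only (exact permutation test, p = 0.037, adjusted p = 0.23). None of the 25 classes separated those groups of tiles after adjustment. Whether an acidic residue at position 2 affects the activities differently within a tile is left open by these 6 tiles.

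The last comparison asked whether a motif carries its activity with it. Each of 8 motifs was measured in 23 or 24 other tiles. In activation the 190 resulting elements differed from their recipient tile by a median of 0.00 over recipients (SD over recipients 0.22; p = 1, sign-flip permutation test), and 2 lay above the control range. In repression the median was 0.05 (SD over recipients 0.17; p = 0.19 by permutation), and 2 lay above the control range. For no motif did the difference pass adjustment over the 8 motifs, with a lowest adjusted p of 0.71 in activation and 0.17 in repression (unadjusted permutation p = 0.022, for the motif of Q2HR71_028). By limma, 16 of the 190 scored higher and 7 lower than their recipient in activation, and 4 and 1 in repression. In its own tile the motif from Q2HR71_028 was part of an element scoring 4.63 ± 0.10 (SD, n = 2). In the other tiles its elements had a median activation score of 0.38.

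**Figure D3:**
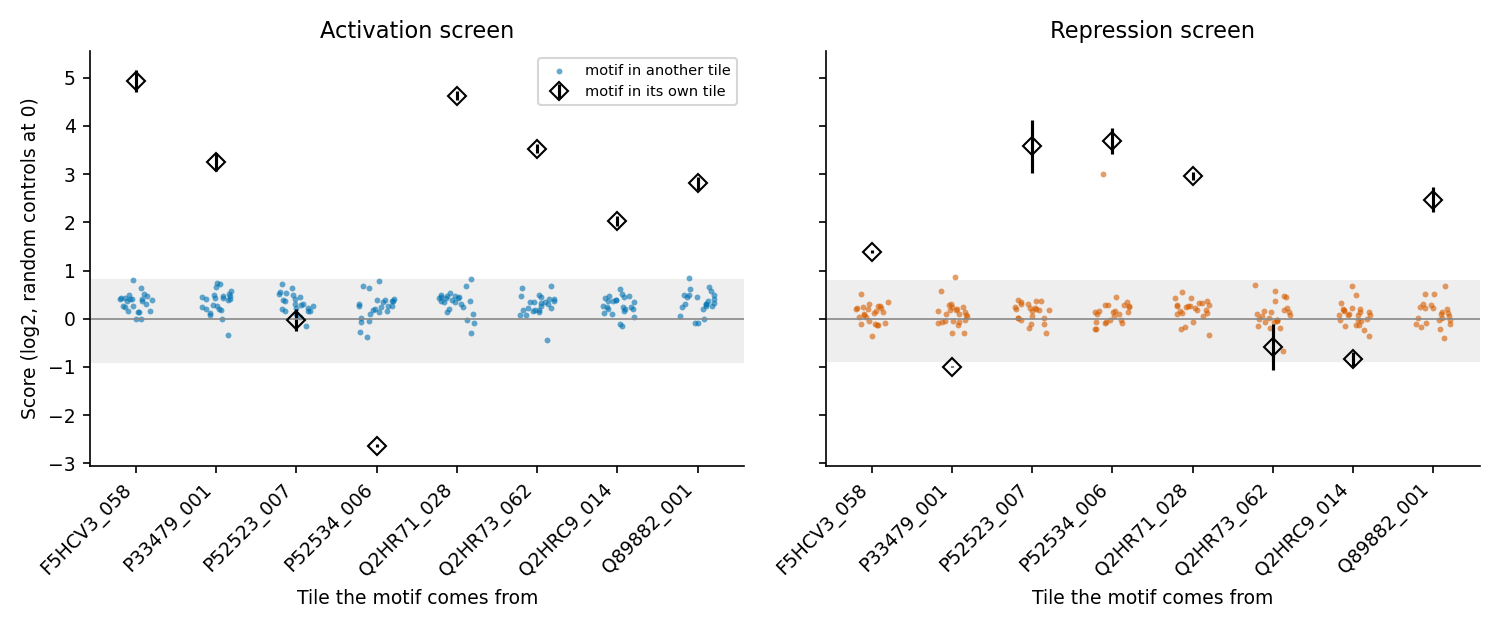
Scores (y axis, log2, random controls at 0) of 8 motifs named by their tile of origin on the x axis, in the activation screen (left) and the repression screen (right). Dots are the motif placed into each of up to 24 other tiles, diamonds with SD bars (n = 2) are the tile of origin, and the grey band is the control range. In each screen 2 of the 190 dots are above the control range, and the highest, for the P52534 motif in repression, is at 3.01.

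The artificial constructs placed 16 motifs into an unrelated sequence in forms labelled 1X, 2X, 3X, 3X-full and 4X, beside a form without a motif labelled 0X. The 0X form scored -0.18 in activation (adjusted p = 0.38, edgeR) and 0.24 in repression (adjusted p = 0.49, edgeR). None of the 77 artificial constructs lay above the control range for activation, and the highest scored 0.64. For repression 6 lay above it. The step from 1X to 4X changed activation by a median of 0.28 (adjusted p = 0.26, permutation test over 16 motifs) and repression by 0.04 (adjusted p = 0.85 by permutation).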

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

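The tests of a property outside the motif, of the basal signal and of the motifs placed into other tiles, and the comparison of tile groups, were chosen after the results were seen.

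A test of the difference between the screens singled out 65 of 351 mutants (18.5%) in the 18 tiles that scored higher in both screens, because their change from the unmutated tile was not the same in both (limma, adjusted p under 0.05). The activation minus repression difference was negative for 40 and positive for 25, and 13 changed in opposite directions. At an unadjusted p under 0.05 there were 127. The screens differ in reporter and day, so their scores are not on one scale and a difference in size need not be a difference in residues.

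Tiles below the random controls in the activation screen were weighed first, though that all 21 scored higher for repression is fixed by a set with no tile higher in neither screen and was not weighed. An element-specific lean toward the Unbound fraction, if random sequences share it, would give random controls with scores running opposite in the screens. Their Pearson's r was 0.28 (95% bootstrap interval -0.04 to 0.62, n = 40), which speaks against such a shared lean. The controls ran only from -1.18 to 0.67 in activation, while the tiles reached -2.91. A lean of these tiles alone is therefore left open. Whether a property of the tile outside its motif takes part was left open: in the 10 tiles below the control range the 1A-4A-5A mutants changed by a median of 0.00, but in both directions, from -0.55 to 1.60, with 2 tiles rising by over 0.5 (permutation p = 1). Whether repression by the motif lowers a basal signal of the minimal promoter was left open too. Of the 21 tiles, 15 had enough mutants for a within-tile r between activation and repression differences. The median r was -0.24 (permutation p = 0.04). It was negative in 13 of the 15 tiles, with a range from -0.93 to 0.49.

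For the motifs without activity in other tiles, too few counts cannot account for the result, since the highest 95% upper bound of the mean activation difference over the 8 motifs was 0.18. The tiles of origin of 6 of the 8 motifs scored above the control range for activation (2.03 to 4.94). For 5 of the 8, the 1A-4A-5A mutant fell by over 1 in its own tile (-4.34 to -2.58, limma adjusted p under 0.05). A tile of origin can also need a site that was not moved. In P33479_001, whose placed motif was residues 4-10, 1A-4A-5A at 14-20 took activation from 3.25 to -0.63 (limma adjusted p of the difference 7e-94). The motif may therefore be needed in its tile without being enough elsewhere, a hypothesis found on these data, and protein levels of the new elements were not measured. An exception is F5HCV3_058, whose placed motif was hardly needed at home (4.94 to 4.17 with 1A-4A-5A, on a library with a count of 5).

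Repressing tiles called in that screen only were compared with those called in both for their losses in repression. Summed over 23 classes, the difference between 16 and 8 tiles had a p of 0.075 by random permutation, which leaves open whether the groups depend on different residues. With each difference divided by the score of the unmutated tile, the p by random permutation was 0.64. Stronger tiles having more to lose may account for what difference there is. The median repression score was 2.45 in all 25 tiles called in repression only and 1.79 in all 18 called in both, a wider set than the tiles tested.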

How the results depend on the processing

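Among the alternatives, the protein as the unit, the omission of elements at a count of 5 and tiles chosen on replicate 1 were added after the results were seen. Of the values that answer a comparison, 211 stayed within the limits set for them, and 12 moved. The limit for counts was wide. TMM took elements lower from 494 to 739 in activation and from 367 to 548 in repression, and both counted as staying. In activation the share of calls that were higher went from 65.5% to 49.0% with TMM, so the split depends on the centring. With the control range in place of the adjusted p, 607 elements were higher and 241 lower for activation, with 10 tiles lower, and 172 elements and 4 tiles were lower for repression. In tiles past the threshold alone, 78 mutants rose in activation and 28 in repression, which leaves out by construction the 189 and 66 that rose in other tiles. In those tiles 17 classes were lower in activation and 25 in repression. The protein as the unit was applied only to classes over all tiles. With tiles chosen on replicate 1 and differences from replicate 2, 16 and 25 classes were lower. Acidic residues at position -1 in activation then lost the call they had in tiles past the threshold, a class not called over all tiles. Why more classes passed was not tested. Among elements past the threshold in at least 1 screen, r between screens was -0.11, and -0.05 for mutant differences. Leaving out each replicate gave -0.10 to -0.09 for mutant differences. The artificial 4X construct of the P52523 motif, not called in activation at 0.04, reversed to -0.29 with TMM and -0.26 with DESeq2's size factors, which shift all scores down. Single classes were set against the fit over all tiles. There 451 values stayed as they were, 35 gained a call, 3 lost it and 11, of 6 uncalled results, moved. Staying means called or uncalled as before or, with a replicate left out, within the SD over tiles. The lost calls were proline at position 3 in activation (-0.43 with the protein as the unit, -0.28 with the tile) and 1L-4L-5L in repression (-0.29 without a count minimum and -0.26 with the protein as the unit, from -0.33). The proline median thus grew as its call was lost, and the cause was not tested. The gene lists were not run.

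Without the replicate block, the calls were 942 higher and 490 lower for activation and 708 and 363 for repression. Mutants then numbered 542 lower and 235 higher for activation and 556 and 87 for repression. Same-numbered fractions deviated together with correlations of 0.096 and 0.099.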

Other observations

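The artificial series and the exceptions named here were looked at after the results were seen, while the predictions on shared residues and on more than 1 motif site were written before their tests.

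A substitution in P03186_304 moved the screens in opposite directions. Tryptophan at position 4 took its repression score from -0.44 to 4.17 ± 0.14 and its activation score from 1.31 to -0.55 ± 0.08 (SD, n = 2; adjusted p of the differences 7.3e-06 and 1.3e-24 by limma). Among the motifs placed into other tiles, P09246_059 with the P52534 motif scored 3.01 ± 0.08 for repression against 0.74 without it (SD, n = 2; adjusted p of the difference 6.5e-05 by limma). For repression the P52523 motif in the artificial sequence scored 0.32 ± 0.09 as 1X, 1.54 ± 0.14 as 2X, 0.42 ± 0.08 as 3X, 2.86 ± 0.13 as 3X-full and 2.85 ± 0.36 as 4X (SD, n = 2). The 1X and 3X forms were not called (edgeR adjusted p = 0.35 and 0.17).

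The hypothesis that the same residues carry both activities was tested in 8 of the 18 tiles higher in both screens. The others had too few mutants for a correlation. Over the mutants of a tile, activation and repression differences had a median Pearson's r of 0.82, positive in 8 of 8 tiles (0.62 to 0.95). The exact sign-flip p of 0.062 is the smallest that 8 tiles can give, so that test could not pass and the range is what speaks for it. This is consistent with shared residues, though a change of protein level by the mutants would give the same and was not measured.

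The hypothesis that another motif site softens the loss of the first predicted a smaller loss from 1A-4A-5A in tiles with more than 1 named site. The activation screen did not show it, with a median of -2.55 in 20 such tiles against -1.96 in 14 (difference -0.59, 95% bootstrap interval -1.52 to 0.47, permutation p = 0.17). The interval ends just under the predicted softening of at least 0.5. In repression the medians were -2.14 in 23 tiles and -1.35 in 20 (difference -0.79, 95% bootstrap interval -1.37 to 1.17, permutation p = 0.11). That interval includes the predicted softening of at least 0.5, so repression leaves it open. Sites that overlap, as in F5HCV3_060, were counted as separate, and there a mutant of one site also changes the other. Such tiles could not show a softening, so neither screen decides the question.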
